A study of Homo sapiens with 6 samples.

How the data were processed

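Total RNA was taken with TRIzol from Cal27 cells after lentiviral knockdown of DAZAP1 (3 samples) or as negative control (3 samples), and the libraries were sequenced on an Illumina platform, per the labels' protocols. The treatment protocol names an empty vector for the control and the series' design text a control sequence, and nothing used here settles which it was. The authors deposited a table of raw counts and a table of FPKM for 30947 genes, each with 6 columns of values. The submitters' processing notes name the build GRCh38.p13 and Bowtie, with no role or version. The counter, the annotation release, the strandedness and the filters are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart. The deposited counts are whole numbers with a different total in each column. The deposited FPKM values, per the table itself, are those counts divided by 1 length per gene and by the library total: the implied length differed between libraries by at most 0.009 on the log2 scale over 10061 genes with at least 100 counts in every library, with a median of 2786 bp. No gene was at 0 in all libraries, and no line of the table lacked a gene identifier. A symbol was missing for 8026 genes, and 229 shared a symbol with another gene. Coordinates and symbols are those of the deposited tables. Biotypes, taken from GENCODE release 29 by Ensembl identifier, were found for 29965 genes.

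The columns carry other names than the samples. They were matched by prefix and replicate number, with columns starting with N taken as control and columns starting with SH as knockdown, and all 6 columns were matched. The order of replicates within a group rests on these numbers alone.

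The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10), which left 15374, libraries were scaled by TMM (factors 0.9875 to 1.013) and knockdown was compared with control by the quasi-likelihood F test (glmQLFit and glmQLFTest, robust) with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values use the TMM-scaled totals, and means are given with the SD over 3 libraries. The totals of 16333542 to 18955230 counts per library set the precision. The biological coefficient of variation was 3.13%, and differences between libraries of a group exceeded Poisson counting noise by a factor (chi-square per degree of freedom) of 2.68 to 2.79 in the control and 1.86 to 2.00 in the knockdown, over genes with at least 50 counts in a pair. For comparisons of a single value, 3 libraries against 3 cannot give an exact permutation p below 0.1.

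Before the data were examined, 28 gene lists and the rule for naming genes were fixed. Named are DAZAP1, the 10 largest rises and 10 largest falls among protein-coding genes that passed, had a mean of at least 5 CPM in the higher group and did not overlap between groups, the 5 smallest p-values in each direction, up to 4 members of each list with the smallest adjusted p, and COX16, KITLG and SLC7A11. Not every gene that the rule picks is named in the text. Any other gene was chosen after its values were seen. The lists cover interferon-stimulated genes, antigen presentation, inflammatory cytokines and NF-kB targets, the amino acid and unfolded protein responses, NRF2 targets, cholesterol and fatty acid synthesis, immediate early genes, YAP/TAZ targets, TGF-beta, WNT and NOTCH targets, cytosolic ribosomal proteins, histones, splicing factors, genes tied to DAZAP1, cytochrome c oxidase, other respiratory complexes, mitochondrial messenger RNAs, glycolysis and hypoxia, S phase, G2/M phase, p53 targets, apoptosis, EMT, epithelial adhesion, matrix remodelling, keratinocyte differentiation, basal keratins, leukocyte markers and markers of fibroblasts, endothelium and neurons. Each was tested against the other genes with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance 1 way, or in either direction, and does not compare them with other genes.

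The alternatives were DESeq2 1.42.0, median-of-ratios, upper-quartile and library size scaling, no filter on low counts and a stricter filter (at least 1 CPM and 10 counts in every library of a group), limma voom with sample weights, the replicate number as a block, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1) and on genes with a mean FPKM of at least 1, and a gene length trend removed. Added after the data were seen were a GC content trend removed, libraries thinned to 1 depth, list tests with a length or GC trend removed, and list tests without genes that carry a 3′ UTR sequence.

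The 3′ UTRs were those of the protein-coding transcript with the longest coding sequence per gene in GENCODE release 29, at least 50 bases long. For each 7-base sequence of the DAZAP1 transcripts, genes with and without it were compared by a z score on log2 fold changes, limited to 3 in size, after trends with 3′ UTR length, base composition and expression were removed, and the lowest score was set against 1000 shuffles of the genes. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 ran these steps, and Matplotlib 3.10.9 drew the figures.

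The steps were tested on simulated data. Counts were drawn for the 15374 genes from the observed means and library sizes, with 50 genes changed at each fold. In the data 54.2% of the genes passed, which makes the Benjamini-Hochberg cut less strict there. The shares recovered and falsely called below hold for the simulated setting and do not carry over. The edgeR test recovered 48% of the genes changed 1.25-fold, 72% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, and 17 of 15174 unchanged genes were called, 9.9% of 171 calls. DESeq2 recovered 44%, 66%, 88% and 88%, with 2 unchanged genes among 145 calls. Camera called 10 of 10 lists shifted by 0.2 and 0 of 10 unshifted lists, but the simulated genes varied independently, so this does not test the preset correlation. A length trend of 0.2 put into the simulated libraries was 0.002 after removal. The 7-base search, over 12055 genes, found 19 of 20 sets given an effect of −0.1 and called 0 of 20 without an effect. The sets without an effect came from the same kind of shuffle that sets the limit, so few calls were fixed in advance. Only common sequences were given an effect, whereas the search took any carried by at least 50 genes.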

Results

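Gene expression was measured by RNA sequencing in Cal27, a human oral squamous cell carcinoma line, after lentiviral knockdown of DAZAP1 and in negative control cells. The labels describe the control both as empty vector and as a control sequence, so whether it carried a hairpin is not known here. DAZAP1 is an RNA-binding protein of the hnRNP family with known roles in splicing and translation. Each group held 3 libraries made from total RNA, 6 in all. The counted totals were 18547236, 18955230 and 18932743 in control replicates 1 to 3 and 17815862, 16930894 and 16333542 in knockdown replicates 1 to 3. At least 1 count was found for 23423 to 23545 genes per control library and for 23856 to 24059 genes per knockdown library. Mitochondrial genes took 2.87 to 2.96% of the counts in the control and 3.09 to 3.19% in the knockdown, mitochondrial ribosomal RNA 0.231 to 0.238% and 0.194 to 0.2%, and genes of cytosolic ribosomal proteins 4.94 to 5.13% and 4.34 to 4.44%. The comparison asks how gene expression in this line differs when DAZAP1 is reduced.

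DAZAP1 (ENSG00000071626, chromosome 19, 1407569 to 1435687, GRCh38.p13) fell in all 3 knockdown libraries. Its level was 262.0, 277.4 and 256.5 CPM (counts scaled to the library total) in the control libraries and 73.5, 77.7 and 67.4 CPM in the knockdown libraries. The means were 265.3 ± 10.9 and 72.9 ± 5.20 CPM (SD, n = 3 each), a log2 fold change of −1.86 ± 0.038 (SE; adjusted p = 1.67e-39, edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), or 3.64-fold lower.

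The rises with the smallest p-values included a lipid enzyme and a chemokine. SCD (ENSG00000099194, chromosome 10, 100347233 to 100364826), the desaturase that makes monounsaturated fatty acids, rose from 140.8 ± 4.47 to 823.2 ± 12.99 CPM (SD, n = 3 each; log2 fold change 2.55 ± 0.026 SE). The monocyte chemokine CCL2 rose from 188.5 ± 6.66 to 935.1 ± 12.1 CPM (log2 2.31), OLR1, a receptor of oxidised LDL, by 3.37 and the water and glycerol channel AQP3 by 2.45 on the log2 scale. The 5 falls with the smallest p-values included ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374370), an inhibitor of lipoprotein lipase, from 53.9 ± 2.51 to 3.60 ± 0.293 CPM (log2 −3.90 ± 0.092 SE), and ADAMTS1 (ENSG00000154734, chromosome 21, 26835755 to 26845409), a secreted metalloproteinase, from 414.3 ± 9.15 to 116.2 ± 3.90 CPM (log2 −1.83 ± 0.029 SE). The RNA helicase DDX39A (log2 −1.93), the epithelial 14-3-3 protein SFN (−0.94) and IER3 (−1.04) were the others. The groups did not overlap in any of these genes, with all 3 knockdown values on 1 side of all 3 control values. The genes were picked for small p-values, so this separation was close to fixed by the choice and is no further support. Of all genes tested, 58.9% did not overlap either.

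Among genes with at least 5 CPM in the higher group, other large rises were in OLFM4 (log2 5.15), the sterol exporter ABCG1 (4.96), the immunoglobulin receptor PIGR (4.85), the stress factor NUPR1 (4.46), TNFSF18 (3.67), the tryptophan-degrading enzyme IDO1 (0.467 to 5.37 CPM), PGLYRP4 (3.19) and the interferon-induced XAF1 (3.12). These 8 genes had few control counts, for example 6, 8 and 18 for OLFM4 and 6, 6 and 0 for ABCG1 in replicates 1 to 3, so their folds are less precise. The other large falls were in the cytokine IL11 (−2.78), ENTPD3 (−2.57), the acyltransferase GPAT3 (−2.51), the IL-33 receptor IL1RL1 (−2.48), the drug efflux pump ABCG2 (−2.33), SERPINB2 (−2.19), RNF223 (−2.16) and TMCC3 (−1.92). The annotated 3′ UTRs of ADAMTS1, GPAT3, ABCG2 and TMCC3 hold the 7-base sequence AGATTGT, which also lies in the DAZAP1 transcript, or its 6-base core GATTGT followed by A. Of the other genes named here, MBNL1, AEN, ZMAT3, CYCS, TNC, COL17A1, JUN, PHLDA1, NT5E and RPL14 also carry it and fell, ITGAM carries it and did not pass the test, and SCD, SLC7A11, IFIT2, SOD2 and CDH5 carry it and rose. Such sites are common. Of 12055 genes with a searched 3′ UTR, 445 hold AGATTGT followed by A, 1098 others AGATTGT, and 539 only the core followed by A. A site in a named gene therefore does not by itself tie its change to the sequence.

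**Figure D1:**
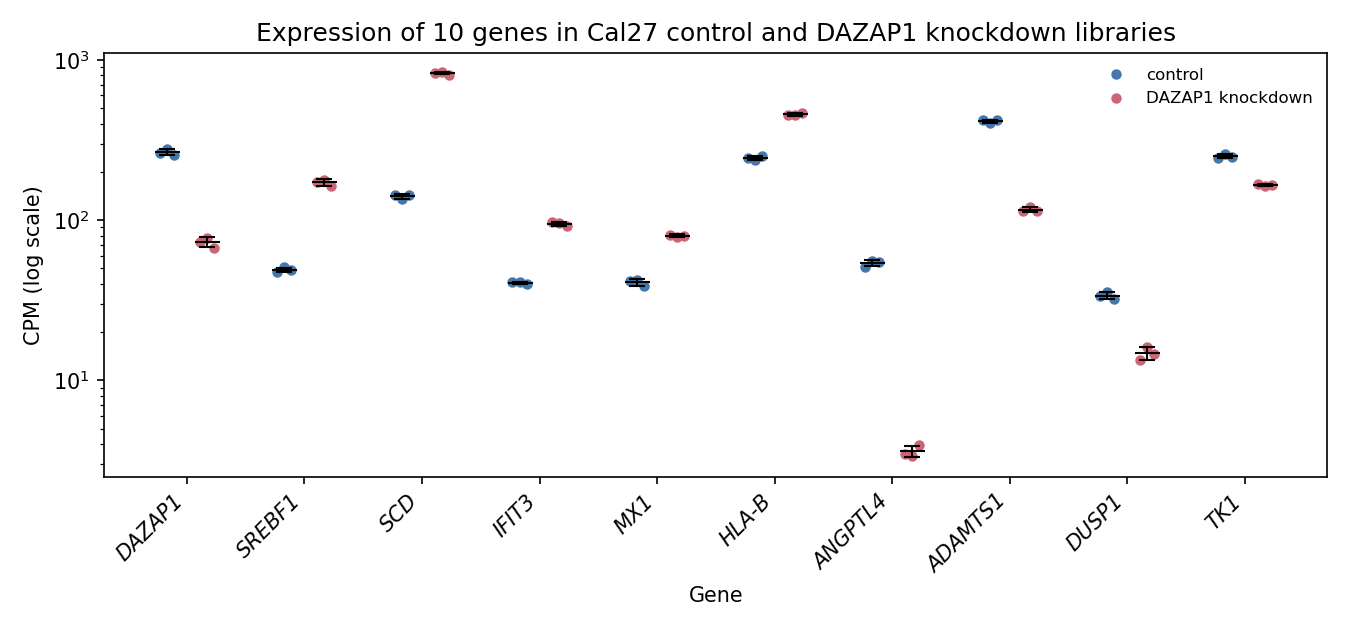
Expression of 10 genes in 3 control and 3 DAZAP1 knockdown Cal27 libraries, with genes on the horizontal axis and CPM on a logarithmic vertical axis; each point is a library, the long bar the mean and the short bars the SD. DAZAP1 lay at 256.5 to 277.4 CPM in the control and 67.4 to 77.7 CPM in the knockdown, and the groups did not overlap in any of the 10 genes, of which DUSP1 was chosen after its values were seen. The others apart from DAZAP1 were picked for small p-values, so their separation follows largely from that choice.

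Of 15374 genes tested, 4131 were higher and 4208 lower in the knockdown at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 54.2% of the genes. Most changes were small, with a median absolute log2 fold change of 0.374 among the genes that passed. A change of 2-fold or more was found for 794 genes that rose and 277 that fell, so 74.1% of these were higher. These counts depended on the scale: with limma on log2(FPKM + 1) they were 144 and 61, and 136 and 57 on genes with a mean FPKM of at least 1. The values of the groups did not overlap for 9051 genes (58.9%), where chance gives 10%. Among the 12555 protein-coding genes tested, 3629 rose and 3911 fell. The labels do not say that the libraries of a group come from separate cultures or infections, so the p-values measure only the spread between these libraries, which belong to 1 knockdown construct as far as the labels tell. The column names of the count table were matched to the samples by their prefix and number, and the level of DAZAP1 in each column went with that match.

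Gene lists fixed before the data were examined were tested with camera and Benjamini-Hochberg adjustment over the 28 lists, and 15 passed, 7 higher and 8 lower than the other genes. With a correlation between genes estimated from these libraries in place of the preset 0.01, 3 lists passed, all higher. Some lists lost their call although the estimate lay below the preset value. It was 0.009 for S phase, 0.003 for immediate early genes, −0.002 for basal keratins and −0.025 for TGF-beta, WNT and NOTCH targets. A call lost in this form of the test therefore does not by itself show that the members vary together. The list with the smallest p held interferon-stimulated genes. Of its 45 measured members 39 rose, 1 fell and 5 did not pass, and the counts adjusted over the list alone were 39 and 1. The antiviral genes IFIT3 (log2 1.22 ± 0.048 SE), IFIT2 (1.20), MX1 (0.96) and DDX60 (1.39) rose, with IFIT3 going from 40.7 ± 0.602 to 94.6 ± 2.96 CPM (SD, n = 3 each). ISG15, picked after its value was seen, was at −0.07 and did not pass. The median was 0.694 (adjusted p = 3.98e-13 for camera and adjusted p = 0.0231 with an estimated correlation). In the same libraries the leukocyte marker PTPRC had 2, 0 and 0 counts in the control and 0, 0 and 1 in the knockdown, LYZ 5, 2 and 1 and 2, 0 and 3, CD3E 0, 0 and 1 and 6, 3 and 1, and CD14 22, 11 and 17 and 43, 44 and 31.

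Among the lists that rose, cholesterol and fatty acid synthesis had the next smallest p, with 26 of 33 measured members higher, 2 lower and 5 not past the test, and 27 and 3 when adjusted over the list alone. Besides SCD, the lipogenic transcription factor SREBF1 rose from 48.9 ± 1.52 to 171.9 ± 7.84 CPM (SD, n = 3 each; log2 1.81 ± 0.041 SE) and fatty acid synthase FASN by 1.11 on the log2 scale. The median was 0.475 (adjusted p = 5.8e-09, and adjusted p = 0.0231 with an estimated correlation). In the list of the amino acid response and unfolded protein response, 33 of 42 members rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone. The stress cytokine GDF15 (1.36), DDIT4 (0.84), the serine synthesis enzyme PSAT1 (0.66) and the mitochondrial folate enzyme MTHFD2 (0.70) rose. Its median was 0.329 (adjusted p = 8.02e-08, and adjusted p = 0.0231 with an estimated correlation).

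Antigen presentation genes rose in 17 of 19 cases, none fell and 2 did not pass, and adjusted over the list alone 17 rose and 1 fell. HLA-B went from 244.5 ± 7.57 to 457.5 ± 8.82 CPM (SD, n = 3 each; log2 0.90), and the peptide transporter TAP1 (0.87), TAPBP (0.47) and CANX (0.31) rose too. The camera result (adjusted p = 1.18e-06, median 0.377) was lost with an estimated correlation (adjusted p = 0.0919 with an estimated correlation). Genes of G2/M phase and mitosis were higher in 23 of 36 cases and lower in 2, with 11 not past, and 24 and 2 when adjusted over the list alone. CENPF (0.54), TOP2A (0.44), HMMR (0.83) and KIF20A (0.60) rose (median 0.167, adjusted p = 0.000194, but adjusted p = 0.0919 with an estimated correlation). Basal and stress keratins with basal regulators held 11 higher, 2 lower and 4 other genes out of 17, also when adjusted over the list alone. KRT17 (1.23), KRT5 (0.51) and KRT8 (0.39) rose and the hemidesmosome collagen COL17A1 fell by 0.70 on the log2 scale (median 0.281, adjusted p = 0.014, but adjusted p = 0.146 with an estimated correlation). In the list of TGF-beta, WNT and NOTCH feedback targets, 13 of 28 genes rose, 5 fell and 10 did not pass, in the same numbers adjusted over the list alone. The NOTCH ligand JAG1 (0.78), the NOTCH target NRARP (1.11) and LTBP2 (1.18) rose (median 0.23, adjusted p = 0.0243, but adjusted p = 0.148 with an estimated correlation).

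**Figure D2:**
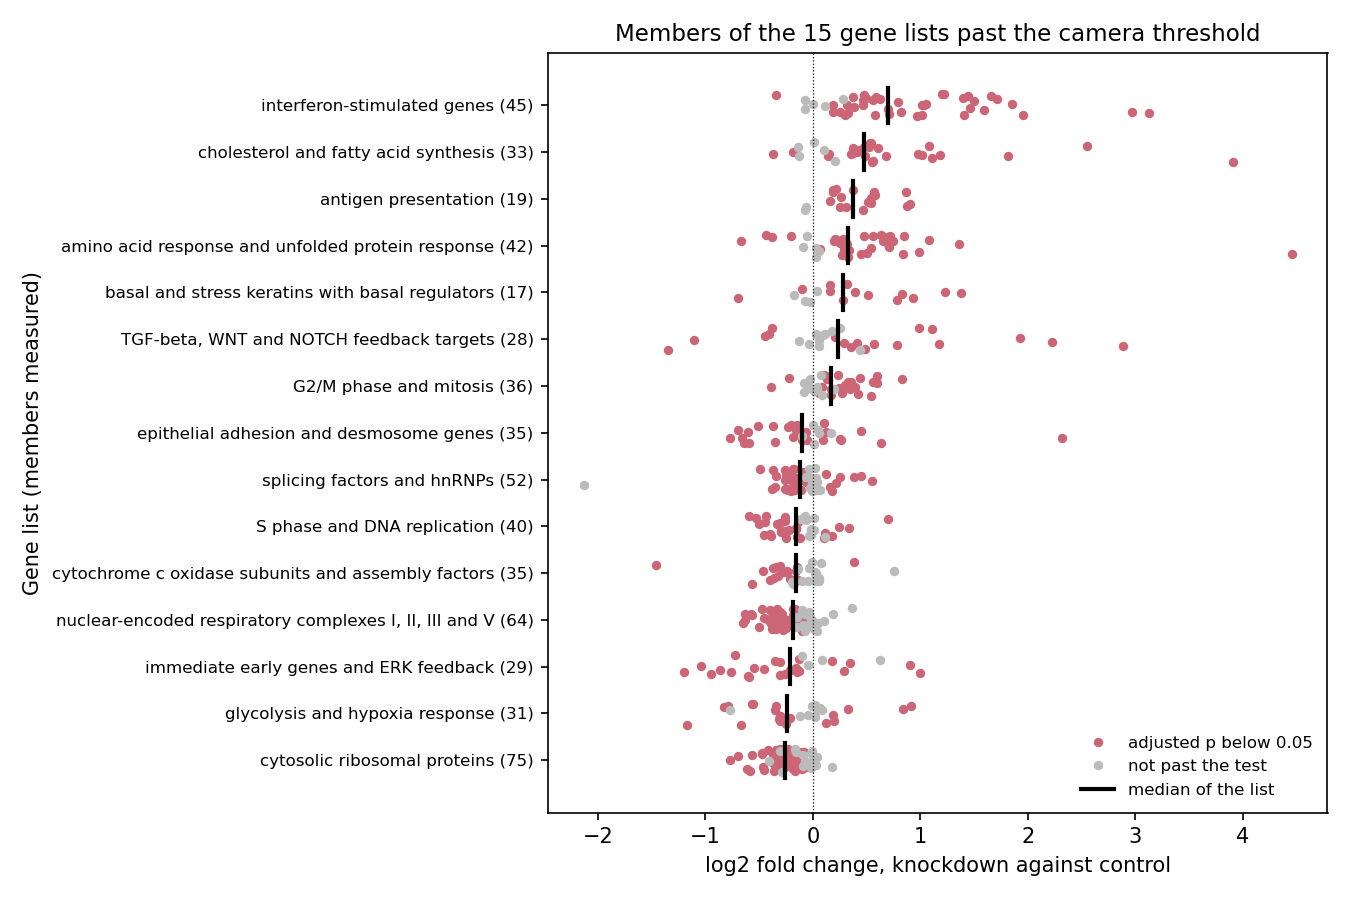
Log2 fold change (knockdown against control, horizontal axis) of the measured members of the 15 gene lists past the camera threshold (vertical axis); each point is a gene, coloured where its adjusted p was below 0.05 and grey otherwise, and the thick line is the median. The medians ran from −0.261 for cytosolic ribosomal proteins to 0.694 for interferon-stimulated genes.

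The list with the smallest p among those lower in the knockdown held cytosolic ribosomal proteins. Of 75 members, 58 fell, none rose and 17 did not pass, and 61 fell and none rose when adjusted over the list alone. RPL24 fell from 510.2 ± 21.1 to 298.9 ± 10.6 CPM (SD, n = 3 each; log2 −0.77 ± 0.027 SE), and RPL6 (−0.42), RPL14 (−0.61) and RPS2 (−0.34) fell as well. The median was −0.261 (adjusted p = 4.21e-10), and the call was lost with an estimated correlation (adjusted p = 0.221 with an estimated correlation). These genes have many processed pseudogenes, so each value is uncertain as far as reads were divided among copies. Nuclear-encoded subunits of respiratory complexes I, II, III and V fell in 45 of 64 cases, none rose and 19 did not pass, with the same numbers adjusted over the list alone. Subunits of ATP synthase (ATP5MC1, −0.63, and ATP5F1D, −0.45), complex III (UQCRC1, −0.40) and complex I (NDUFB2, −0.57) fell (median −0.188, adjusted p = 4.43e-07, but adjusted p = 0.151 with an estimated correlation). Lists of random genes matched on length and expression had a median of −0.101, and 240 of 10000 such lists were as low as the respiratory genes, or 26 of 10000 with a gene length trend removed. Among cytochrome c oxidase subunits and assembly factors, 18 of 35 fell, 1 rose and 16 did not pass, also when adjusted over the list alone. NDUFA4 (−0.40), COX4I1 (−0.28), COX5A (−0.32) and COX7B (−0.31) fell (median −0.161, adjusted p = 0.0103, but adjusted p = 0.276 with an estimated correlation). Mitochondrially encoded messenger RNAs were split, with 4 higher, such as MT-CO3 (0.43) and MT-ND4L (0.12), 3 lower, such as MT-ND1 (−0.18) and MT-ND2 (−0.12), and 6 of 13 not past the test. Adjusted over the list alone, 5 were higher and 4 lower, and camera gave an adjusted p = 0.796.

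Immediate early genes and ERK feedback genes were lower in 20 of 29 cases and higher in 5, with 4 not past, and 21 and 5 when adjusted over the list alone. IER3, JUN (−0.95) and PHLDA1 (−0.72) fell, while the EGF receptor ligand EREG rose by 1.00 on the log2 scale (median −0.216, adjusted p = 0.00174, but adjusted p = 0.0919 with an estimated correlation). Of 40 genes of S phase and DNA replication, 23 fell, 7 rose and 10 did not pass, in the same numbers adjusted over the list alone. Thymidine kinase TK1 (−0.59), the ribonucleotide reductase subunit RRM1 (−0.45) and CLSPN (−0.53) fell and the helicase subunit MCM6 rose by 0.70 (median −0.153, adjusted p = 0.0081, but adjusted p = 0.146 with an estimated correlation). Splicing factors and hnRNPs were lower in 30 of 52 cases, higher in 8 and not past the test in 14, with 31 lower and 8 higher adjusted over the list alone. CELF1 (−0.38) and MBNL1 (−0.37) fell, and QKI (0.55) and HNRNPA1 (0.25) rose (median −0.119, adjusted p = 0.0124, but adjusted p = 0.254 with an estimated correlation). In glycolysis and the hypoxia response, 16 of 31 genes fell, 6 rose and 9 did not pass, and 17 and 6 adjusted over the list alone. NDRG1 (−1.17), hexokinase HK1 (−0.56) and lactate dehydrogenase LDHA (−0.34) fell and DDIT4 rose (median −0.237, adjusted p = 0.0195, but adjusted p = 0.184 with an estimated correlation).

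Epithelial adhesion and desmosome genes fell in 21 of 35 cases, 8 rose and 6 did not pass, in the same numbers adjusted over the list alone. COL17A1, the laminin chain LAMB3 (−0.59) and plectin PLEC (−0.64) fell and the claudin CLDN1 rose by 0.64. This list passed narrowly (median −0.102, adjusted p = 0.0437, but adjusted p = 0.325 with an estimated correlation), and it did not pass without knockdown replicate 3 (adjusted p = 0.0758), with library size as the only scaling (0.0652), with the replicate number as a block (0.0747) or without the genes that carry the 3′ UTR sequence AGATTGT or its core with A (0.142). Over all camera alternatives its adjusted p ran from 0.0178 to 0.325.

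Of the 3 genes tied to DAZAP1 in earlier work, the cystine transporter subunit SLC7A11 rose from 42.7 ± 1.85 to 84.8 ± 0.867 CPM (SD, n = 3 each; log2 0.99), and the KIT ligand KITLG fell by 0.34 and COX16, a cytochrome c oxidase assembly factor, by 1.46 on the log2 scale. COX16 had 60, 65 and 68 counts in the control and 27, 19 and 19 in the knockdown. It overlaps SYNJ2BP on the same strand (53.7 ± 0.66 and 52.9 ± 1.27 CPM), so its value is uncertain. All 3 passed adjusted over the list alone, and camera gave an adjusted p = 0.58 for the list. With all genes that carry the 3′ UTR sequence left out, SLC7A11 among them, the remaining 2 genes were lower and the list passed camera (adjusted p = 0.0437, with a range of 0.0437 to 0.641 over all camera alternatives).

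The other lists did not pass camera, and many of their members changed in both directions. In the p53 target list 6 of 24 genes rose and 14 fell (adjusted p = 0.0829), with the cell cycle inhibitor CDKN1A (−1.02), AEN (−1.08) and ZMAT3 (−0.91) lower and GDF15 higher. Inflammatory cytokines and NF-kB targets held 19 of 34 higher and 11 lower (adjusted p = 0.0509), with CCL2, SOD2 (0.84) and SAA1 (1.40) higher and IL11 lower. For NRF2 targets, redox defence and ferroptosis, 18 of 35 rose and 9 fell (adjusted p = 0.0701), SLC7A11 and the transferrin receptor TFRC (0.36) rising and the ferritin chains FTL (−0.38) and FTH1 (−0.32) falling. Replication-dependent histone genes had 4 of 16 higher and none lower (adjusted p = 0.0595), namely H2AC6 (0.40), H4C9 (0.59), H2BC9 (0.88) and H2AC11 (0.60). The calls of these 4 lists changed when a library was left out. The p53 and NRF2 lists each passed without control replicate 3 (adjusted p = 0.0473), the NF-kB list without knockdown replicate 3 (0.0365), and the histone list without control replicate 2 (0.0482) or knockdown replicate 2 (0.0224). Over all camera alternatives the adjusted p ran from 0.0473 to 0.39 for p53, 0.0409 to 0.184 for NRF2, 0.0209 to 0.167 for NF-kB and 0.0209 to 0.184 for the histones. Adjusted over the list alone, the counts of these 4 lists were the same.

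Apoptosis regulators had 16 of 34 higher and 8 lower (16 and 9 adjusted over the list alone; adjusted p = 0.254), with the death ligand TNFSF10 (1.54) and survivin BIRC5 (0.42) higher and cytochrome c CYCS (−0.46) lower. Matrix remodelling and invasion genes had 16 of 32 higher and 13 lower (16 and 14 adjusted over the list alone; adjusted p = 0.438), with the proteases CTSB (0.81), ADAM10 (0.80) and PLAU (0.63) higher and ADAMTS1 lower. Mesenchymal and EMT genes had 10 of 21 higher and 7 lower, also adjusted over the list alone (adjusted p = 0.58), SPARC (0.71) and COL5A1 (0.74) rising and TNC (−0.58) falling. YAP/TAZ targets had 11 of 22 higher and 8 lower, also adjusted over the list alone (adjusted p = 0.189), ANKRD1 (1.21) and IGFBP3 (0.53) rising and AMOTL1 (−0.94) and NT5E (−0.70) falling. Keratinocyte differentiation and cornification genes had 9 of 29 higher and 10 lower (9 and 11 adjusted over the list alone; adjusted p = 0.901), S100A8 (1.22) and KLF4 (0.80) rising and the protease KLK5 (−1.81) and the lipoxygenase ALOXE3 (−1.23) falling.

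Markers of other cell types were tested in the same way. Of 14 leukocyte markers 3 were kept by the filter on low counts, of which CD14 rose (1.34, with 22, 11 and 17 counts in the control and 43, 44 and 31 in the knockdown), CSF1R fell (−0.78) and ITGAM was at −0.26 and did not pass. The median was −0.259 and the mean 0.099, of opposite sign, and the counts were the same adjusted over the list alone (camera adjusted p = 0.796). Of 17 fibroblast, endothelial and neural markers 8 were kept by this filter, of which 4 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.189). The endothelial cadherin CDH5 rose from 14.4 ± 1.59 to 48.3 ± 3.26 CPM (SD, n = 3 each; log2 1.75), the collagen COL1A1 by 0.62, COL1A2 by 1.08 and PDGFRB by 1.75 on the log2 scale. PDGFRB had 7, 6 and 7 counts in the control and 10, 20 and 33 in the knockdown, and without knockdown replicate 3 it did not pass (adjusted p = 0.057, with 0.00024 to 0.226 over all alternatives, edgeR quasi-likelihood test or limma, Benjamini-Hochberg adjustment). Reads from near-identical copies cannot be assigned with certainty because the counting rule was not given in the sources used here, so the values of HLA-B, KRT17, HNRNPA1, SAA1, FTL, FTH1, the histone genes and the mitochondrial genes are uncertain to that degree.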

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

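The GC content and thinning alternatives and the list tests with a trend removed or without carriers of the 3′ UTR sequence were chosen after the data were seen. DAZAP1 stayed lower and past the threshold in all 20 alternatives, with a log2 fold change of −1.91 to −1.71. The number of genes higher was 3163 to 4800 and lower 2756 to 4349, against 4131 and 4208. Which direction held more genes depended on the scale. More were higher with upper-quartile scaling (4800 and 3584 lower), with library size only (4594 and 3763) and on the FPKM scales, and more were lower in the other alternatives. Only limma on log2(FPKM + 1) moved a total by more than 1.5 times, to 2756 lower. On that scale 144 genes rose and 61 fell by 2-fold or more, and 136 and 57 at a mean FPKM of 1 or more, against 794 and 277. A pseudocount of 1 shrinks the folds of low genes. Without each library in turn, 3721 to 3905 genes were higher and 3911 to 4104 lower. All genes called both by edgeR and by an alternative had the same direction, for example 6645 with DESeq2. Of 2489 pairs of another named gene and an alternative, 2481 kept direction and side, 8 lost the call and 0 reversed. The losses were MT-ND2, COL1A2 and PDGFRB on the 2 unfiltered FPKM scales, H2AC11 with DESeq2 and PDGFRB without knockdown replicate 3. The cause was not tested. With an estimated correlation, 3 lists were higher and 0 lower, and by fry, which does not compare a list with other genes, 15 were higher and 9 lower, against 7 and 8. In the other list alternatives 7 to 10 were higher and 7 to 9 lower. Controls and knockdowns share replicate numbers, but samples with the same number did not deviate together (correlations −0.006 to 0.003). No sample correlated best with the sample of its own number in the other group. With the number as a block, 4101 genes were higher and 4206 lower, and among the lists only epithelial adhesion lost its call. In simulated data at this depth, 72% of genes changed 1.5-fold were recovered. Far fewer genes were changed there than passed in the data, so that share does not carry over, though small changes can be missed.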

Other observations

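The groups in the next paragraph, the test of loss of a factor that binds the same sequence, the matched lists with the length trend removed and the leukocyte sum without CSF1R were chosen after the results were seen, and the search for a shared 3′ UTR sequence was prompted by the strongest falls but specified before it was run.

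Further gene groups, a few of whose members are also in the fixed lists, are given as counts of genes past the threshold, with no test of the group. These 13 groups were chosen after values were seen, and further groups were looked at whose number was not recorded, so they are a selection. All 11 measured genes of the MHC class II group were higher in the knockdown, a count that includes CD74 (log2 0.89) and the regulator CIITA (0.98). HLA-DRA went from 18.4 ± 1.16 to 49.0 ± 0.684 CPM (SD, n = 3 each, log2 1.42). All 3 measured peptidylarginine deiminases were higher (PADI2 2.99, PADI3 2.48, PADI1 1.47), as were all 5 butyrophilin 2 and 3 genes and all 3 of S100A7 to S100A9. Of the sterol-responsive genes 5 of 7 were higher, among them the cholesterol exporter ABCA1 (log2 2.24) and MYLIP (1.62), and LPCAT3 (−0.37) and SMPDL3A (−0.38) were lower. The APOBEC3 genes and the APOL genes were each higher in 3 of 4 cases, and of 6 GBP genes 4 were higher and 1, GBP6 (−0.38), was lower. Type IV collagens were higher in 3 of 4 cases (COL4A1 1.22), Frizzled receptors in 6 of 7, with FZD6 (−0.19) lower, and toll-like receptors in 4 of 6 (TLR3 1.39). Dual-specificity phosphatases were lower in 10 of 19 cases and higher in 3. Of 5 cohesin subunits SMC1A, whose 3′ UTR carries AGATTGT, was lower (−1.25) and the other 4 were higher by at most 0.28. HLA-DRB1 and HLA-DRB5 are near-identical copies whose values are uncertain, and several genes of these groups had few counts.

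Genes lower in the knockdown were searched for a 7-base sequence shared with the DAZAP1 transcript, as a short hairpin can also reduce transcripts that match its seed. Of 5927 sequences tested over 12055 genes, AGATTGT had the lowest z (−7.9, against −5.54 as the lowest of 1000 shuffles and −3.68 for DAZAP1 sequences unrelated to it). It was also first among 16157 sequences taken without regard to DAZAP1. The next there, GATTGTA (−7.05) and TGATTGT (−5.14), overlap it and are not in DAZAP1. The DAZAP1 transcripts hold 36.3% of all 7-base sequences, so the presence of AGATTGT in them is in itself weak evidence for the hairpin. AGATTGT lies at 1 place in DAZAP1, chromosome 19, 1418244 to 1418250, in 9 of 11 transcripts. For genes with it followed by A (AGATTGTA, 445 genes, such as ABCG2 and CPEB4), the mean log2 fold change with the trends removed was −0.205 ± 0.023 (SE) relative to genes without a site, with other bases −0.071 to −0.109. With the trends kept, their median was −0.139, against 0.005 without a site. Of the 3749 lower genes with a searched 3′ UTR, 21.8% carry it or its core followed by A, against 14.6% in draws matched on 3′ UTR length. The sequence was picked on these same fold changes, so lower values and an excess of its carriers follow from that choice and are no further support. A seed effect of the hairpin is a candidate explanation for part of the falls, since most lower genes carry no site; it cannot be told apart from loss of a factor that binds the same sequence (−0.205), because the hairpin sequence is not given in the sources used here and 1 construct was compared.

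Ribosomal protein and respiratory chain messenger RNAs were lower together, and technical trends were tested for both. The median of the ribosomal protein genes (−0.261) lay below the 2.5th percentile of random lists matched on gene length (−0.17) or GC content (−0.116). That of the respiratory genes (−0.188) lay below the bound for GC content (−0.122). Similar genes shared part of the falls, as the random lists had medians of −0.103 and −0.047 for the ribosomal genes and −0.03 for the respiratory genes. Members of the random lists were drawn independently, while the estimated correlations were 0.267 and 0.086, so the bounds are too narrow for genes that vary together. The values argue against these trends as the whole cause, but less firmly than the bounds imply. For the respiratory genes the length bound was −0.187, within a margin of 0.02 set after both values were seen. With the length trend removed their median was −0.192, below a bound of −0.165 that is too narrow in the same way, so these bounds do not decide on length. The trend itself was at most −0.073 for any of these genes, which argues against a smooth length trend as the whole cause. Reads moved to pseudogenes would raise these, but the pooled pseudogenes changed by −389.3 CPM while the genes fell by 8038.4 CPM. Lower transcription or stability of these RNAs in the knockdown was not tested.

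Interferon-stimulated genes were higher by 773.8 CPM in all. Leukocytes in the culture would bring their own abundant RNAs. By limits written before the sums were seen, a rise of at most 1 CPM would argue against them, and 1% of the interferon rise would go with them. The pooled leukocyte markers changed by −2.96 CPM, from 13.04 to 10.1, but through CSF1R, which fell from 10.0 to 5.82 CPM. Without CSF1R, which the control already expressed, the sum changed by 1.23 CPM, 0.159% of the rise. That lies between the limits, so the sums do not decide. CD14 went from 0.899 to 2.28 CPM and CD3E from 0.018 to 0.189 CPM, while PTPRC (0.036 and 0.02 CPM) and LYZ (0.144 and 0.097 CPM) stayed near 0 and gave no sign of many leukocytes. Type I and III interferon genes other than IFNE had 11 counts in the knockdown, 8 of them IFNB1, and 0 in the control, while IFNE, which carries the 3′ UTR sequence, had 46 and 109, respectively. A response to a hairpin, or to an unequal dose of virus, may explain the rise, and it cannot be told apart from an effect of DAZAP1 loss, since the labels leave open whether the control carried a hairpin and 1 knockdown construct was compared.

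The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8339 genes by edgeR and 15 lists by camera, and the other splits 0 genes and 4 to 9 lists, so 1 of the 10 splits gave as many genes and 1 of the 10 as many lists. Each of the other splits mixes knockdown and control samples on both sides, so the group difference enters the spread within each side. Few gene calls were thus fixed in advance, and the 0 genes do not show that the edgeR p-values are well set. Each of these splits also keeps part of the group difference, so they do not show whether the list p-values with the preset correlation are too small, which stays open.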
